A study of Mus musculus with 6 samples.

How the data were processed

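RNA sequencing was done on common dendritic cell progenitors, the bone marrow cells that give rise to dendritic cells, from wildtype C57BL/6 mice 6 to 8 weeks old. Per the labels, the cells were flow-sorted into 3 subsets by the surface proteins CD115, encoded by Csf1r, and Ly6C, encoded by Ly6c1 and Ly6c2. The subsets were CD115+Ly6C-, CD115+Ly6C+ and CD115-Ly6C-, with 2 samples each. The labels do not say that the 2 samples of a subset came from separate animals or sorts, so each p-value measures only the spread between these samples, which may be technical. Per the labels' protocols, polyadenylated RNA was selected, fragmented and amplified by PCR. No label mentions unique molecular identifiers, so intervals and floors below cover counting error only. The strandedness of the kit is not stated, so reads in exons shared with an overlapping or antisense gene cannot be told apart. Overlap was read from the start and end of each gene, and shared exons were not checked. Only overlaps with protein-coding genes are named below. Further named genes, Ccr9, Clec7a and F13a1 among them, overlap genes of long non-coding RNA.

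Per the submitters' processing notes, the reads were aligned to mm10 with Bowtie2 and quantified with RSEM. Versions and settings are not given in the sources used here. Each deposited sample table, per the file headers, holds RSEM expected counts, which are estimated and need not be whole, and FPKM. Of the expected counts above 0 that the authors deposited, 12.6% were not whole (tolerance 1e-06). A gene without reads was left out of a sample's table and was taken as 0. The FPKM values in the authors' deposited table of the whole series were those of the sample tables (largest difference 0.0). Of 16135 genes listed in any sample, 778 carried only a number given by the submitters, with 3.56% to 4.18% of the counts of a sample. The other 15357 had Entrez gene identifiers, of which 15332 matched the RefSeq table of GRCm38.p6, the same assembly as mm10. It gave the chromosome, start and end of each named gene, counted from 1. Spreadsheet software had turned 21 symbols into dates, and all 21 were restored from the identifier. RSEM splits reads between near-identical copies by estimation, so values of Ly6c1 and Ly6c2, of the Gimap family, of Ctla2b, of Tmem254b and of Mrgpra2b are uncertain.

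The total of expected counts lay between 17961541 and 19450329 per sample. Expected counts were rounded to whole numbers and tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the subset as group (minimum count 10, minimum total count 15), which left 12127. Scaling was by TMM. All 6 samples entered 1 fit with 1 coefficient per subset and no further term, and the 3 subsets were compared pair by pair. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05, and are written as edgeR adjusted p. The common dispersion was 0.0231, a biological coefficient of variation of 15.2%, with 3 residual and 5.6 prior degrees of freedom. Levels are given as TMM-scaled CPM (counts scaled to a common library size), mean ± SD (n = 2). The SE of a log2 fold change was taken as its size over the square root of F. A gene with 0 counts in a subset was set against a floor of 3 counts over the 2 libraries of that subset. With 1 to 3 counts, the ratio is given with an exact (Clopper-Pearson) 95% interval.

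Before the data were examined, the groups, the test, 29 gene lists, the alternatives and the rule for named genes were fixed. Lists were tested with camera from limma 3.58.1 on the same model, with a preset correlation of 0.01 between genes and at least 5 tested members, and adjusted over the 28 lists tested in a comparison. The list of mitochondrially encoded genes had no member under its symbols and was not tested. Ly6c2 was also on the plasmacytoid dendritic cell and monocyte lists, and Csf1r on the monocyte and cytokine receptor lists. Both encode sorted proteins, so the sort itself bears on their direction there. The list called sort markers holds Csf1r, Ly6c1 and Ly6c2, and also Flt3, Kit, Il7r and Ly6a. The subsets were not told apart by the proteins of these last genes, so a result for the list is not one for CD115 and Ly6C alone. Named genes were, in each comparison, the 7 sort marker genes, and the 10 genes with the largest and the 10 with the smallest log2 fold change. These last had to be past the threshold, with both samples of 1 subset above both of the other and a mean of at least 5 FPKM in the higher subset, and predicted or unnamed gene models were left out. For each list that was called or had at least 3 members past the threshold, up to 4 members with the smallest adjusted p were added, at most 3 in a direction. For each set of genes of 1 subset, 5 were added. The text may name fewer, taken from the top of each part, and the single-gene results of 2 genes are not reported here. A gene counted as a gene of 1 subset when it was past the threshold in both comparisons of that subset, in the same direction, with a log2 fold change of at least 1 in size in both. Because those comparisons share libraries, the overlap that unchanged genes alone give was simulated with 20 draws.

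The alternatives were the size factors of DESeq2, library totals alone, no filter on low counts, a stricter filter (1 CPM in 2 samples and a mean of 1 FPKM), and DESeq2 1.42.0. Others were limma on log2(FPKM + 1) for genes with 1 FPKM in 2 samples, the same with a pseudocount of 0.1 or with no filter, a minimum fold of 1.5 with glmTreat, a replicate block, and the 2 subsets of a comparison alone. Each of the 6 samples was left out in turn. A subset then has 1 sample, which is assumed to vary like the other subsets. For lists, camera with an estimated correlation was run, and fry, which tests whether the genes of a list move on balance 1 way and does not compare them with other genes. Camera with an estimated correlation tests on the 3 residual degrees of freedom of the fit. It can therefore lose a call even where the genes of a list are not correlated. Library totals for the lists, the removal of each library's trend with gene length, and a split of the libraries of a shared subset, 1 for each of its comparisons in both ways round, were added after the data were seen.

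The test was run on simulated counts made from the real means, depths and dispersions, with 200 genes changed in each comparison. For CD115+Ly6C+ against CD115+Ly6C-, on 11925 genes, 16.9% of the 1.5-fold, 66.7% of the 2-fold and 87.5% of the 4-fold changes were recovered, and 11.9% of 126 calls were false. For CD115-Ly6C- against CD115+Ly6C-, on 11914 genes, the shares were 19.7%, 60.6% and 90.9%, with 10.3% of 126 calls false. For CD115-Ly6C- against CD115+Ly6C+, on 11946 genes, they were 9.1%, 64.1% and 82.8%, with 9.9% of 111 calls false. The share of false calls was thus above the nominal rate in these simulations, which held 1 draw each. The data gave 1164, 1844 and 4768 calls in these comparisons, many more than the 200 genes changed here. The adjusted threshold then admits larger p-values, so these shares do not measure recovery or false calls in the data. In simulated counts for the first comparison, 1 list of randomly drawn genes was moved 1.5-fold. It was called, and 0 of the fixed lists were. Simulated genes varied independently of each other, so false calls of lists of correlated genes were not measured. Tables were handled with Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1, and figures were drawn with matplotlib 3.10.9.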

Results

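The samples were 6 polyA-selected RNA libraries of common dendritic cell progenitors from mouse bone marrow, 2 from each of 3 flow-sorted subsets. CD115 is the receptor for macrophage colony-stimulating factor, and Ly6C is a surface antigen carried by monocytes and their precursors. Neither marker's protein level is in the values used here, so both were read through their genes. Expected counts summed to 19450329 and 18956257 in CD115+Ly6C-, 18825536 and 17961541 in CD115+Ly6C+, and 18226415 and 18954719 in CD115-Ly6C-. Between 13307 and 14127 genes had reads in a library. In each library the most abundant entry was 1 of 16294 nucleotides that the submitters numbered themselves, close in length to the mitochondrial genome, with 1.88% to 2.49% of the counts.

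The 3 subsets lay apart along the first principal component of log2 CPM, which held 64.3% of the variance. On it CD115+Ly6C+ stood at -57.3 and -61, CD115+Ly6C- at -5.3 and -6.5, and CD115-Ly6C- at 67 and 62.9. The second component (15.7%) set CD115+Ly6C- apart from the others, and also its libraries from each other (48.7 and 15.9). Across genes, Pearson's r between the log2 CPM of 2 libraries was 0.979 within CD115+Ly6C-, 0.981 within CD115+Ly6C+ and 0.982 within CD115-Ly6C-. It was 0.956 to 0.965 between CD115+Ly6C- and CD115+Ly6C+, 0.948 to 0.959 between CD115+Ly6C- and CD115-Ly6C-, and 0.903 to 0.91 between CD115+Ly6C+ and CD115-Ly6C-. Genes are not independent replicates, so these values describe the libraries only. The libraries of a subset were not copies of the same counts (chi-square per degree of freedom 19.44 to 21.79), which does not show that they came from separate animals or sorts.

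**Figure D1:**
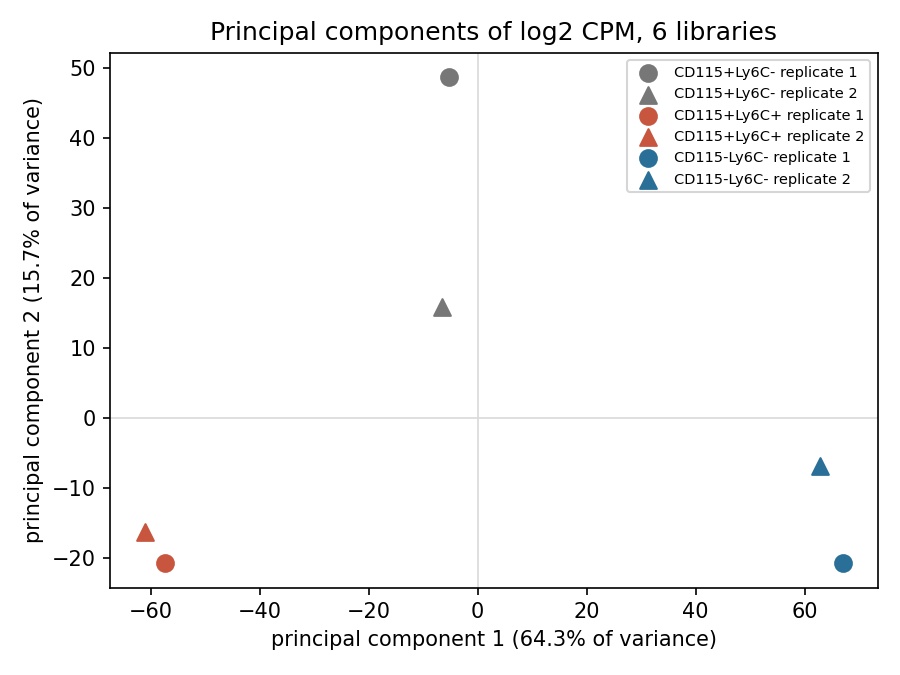
Principal components of log2 CPM for the 6 libraries, with the share of variance on each axis (no unit), color for the subset and shape for the replicate. CD115+Ly6C- lies between CD115+Ly6C+ (-57.3 and -61) and CD115-Ly6C- (67 and 62.9) on the first component.

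Transcripts of the sort markers were read first. Ly6c2 (Entrez gene 100041546, chromosome 15, 75108161 to 75112066 of GRCm38) stood at 1420 ± 27.2 CPM in CD115+Ly6C+, 155 ± 47.7 in CD115+Ly6C- and 51.8 ± 14.1 in CD115-Ly6C- (n = 2 each). Its log2 fold change was 3.20 (SE 0.24) for CD115+Ly6C+ against CD115+Ly6C- and -1.58 (SE 0.23) for CD115-Ly6C- against CD115+Ly6C- (edgeR adjusted p = 4.68e-04 and 0.00391). Csf1r (Entrez gene 12978, chromosome 18, 61105572 to 61131139), the gene of CD115, was at 463 ± 70.0 CPM in CD115+Ly6C-, 542 ± 15.6 in CD115+Ly6C+ and 236 ± 32.5 in CD115-Ly6C-. No difference was detected between the subsets sorted as CD115+ (log2 fold change 0.23 (SE 0.14), edgeR adjusted p = 0.324). In CD115-Ly6C- it was lower than in CD115+Ly6C- by a log2 fold change of -0.97 (SE 0.14) and than in CD115+Ly6C+ by -1.20 (SE 0.14) (edgeR adjusted p = 0.00377 and 4.00e-04). The subset sorted as CD115- thus kept a Csf1r transcript level within 2.30-fold of both others. Ly6c1, the paralog of Ly6c2 with which reads may be shared, stood at 22.1 ± 0.844 CPM in CD115+Ly6C+, 2.7 ± 1.44 in CD115+Ly6C- and 1.13 ± 0.328 in CD115-Ly6C-. Its difference between CD115-Ly6C- and CD115+Ly6C- did not pass (log2 fold change -1.25, edgeR adjusted p = 0.0764), but did without CD115+Ly6C- replicate 1 (0.0395) and with DESeq2 (0.0297).

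Receptors of early progenitors followed the opposite order to Ly6c2. Flt3 (Entrez gene 14255, chromosome 5, 147330741 to 147400489), the receptor whose ligand drives dendritic cell development, stood at 1101 ± 53.6 CPM in CD115-Ly6C-, 662 ± 6.09 in CD115+Ly6C- and 357 ± 21.8 in CD115+Ly6C+. Kit (Entrez gene 16590, chromosome 5, 75574987 to 75656722), the stem cell factor receptor, was at 179 ± 14.5, 101 ± 9.04 and 53.9 ± 7 CPM. Il7r (Entrez gene 16197, chromosome 15, 9506159 to 9529941), a receptor chain of lymphoid progenitors, was at 74.7 ± 7.29, 13.9 ± 0.672 and 1.83 ± 0.46 CPM (n = 2 each). All 3 genes differed in each of the 3 comparisons, with edgeR adjusted p from 2.56e-06 to 0.00599; the largest of these, for Kit in CD115+Ly6C+ against CD115+Ly6C-, became 0.0543 without CD115+Ly6C- replicate 1. Ly6a, which encodes Sca-1, was at 23.2 ± 0.506 CPM in CD115-Ly6C-, 7.34 ± 2.82 in CD115+Ly6C- and 9.07 ± 2.58 in CD115+Ly6C+. It was higher in CD115-Ly6C- than in CD115+Ly6C- and CD115+Ly6C+ (edgeR adjusted p = 0.0096 and 0.00731), and the first of these became 0.0635 without CD115+Ly6C- replicate 1. No difference in Ly6a was detected between CD115+Ly6C+ and CD115+Ly6C- (log2 fold change 0.30 (SE 0.30), edgeR adjusted p = 0.55).

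**Figure D2:**
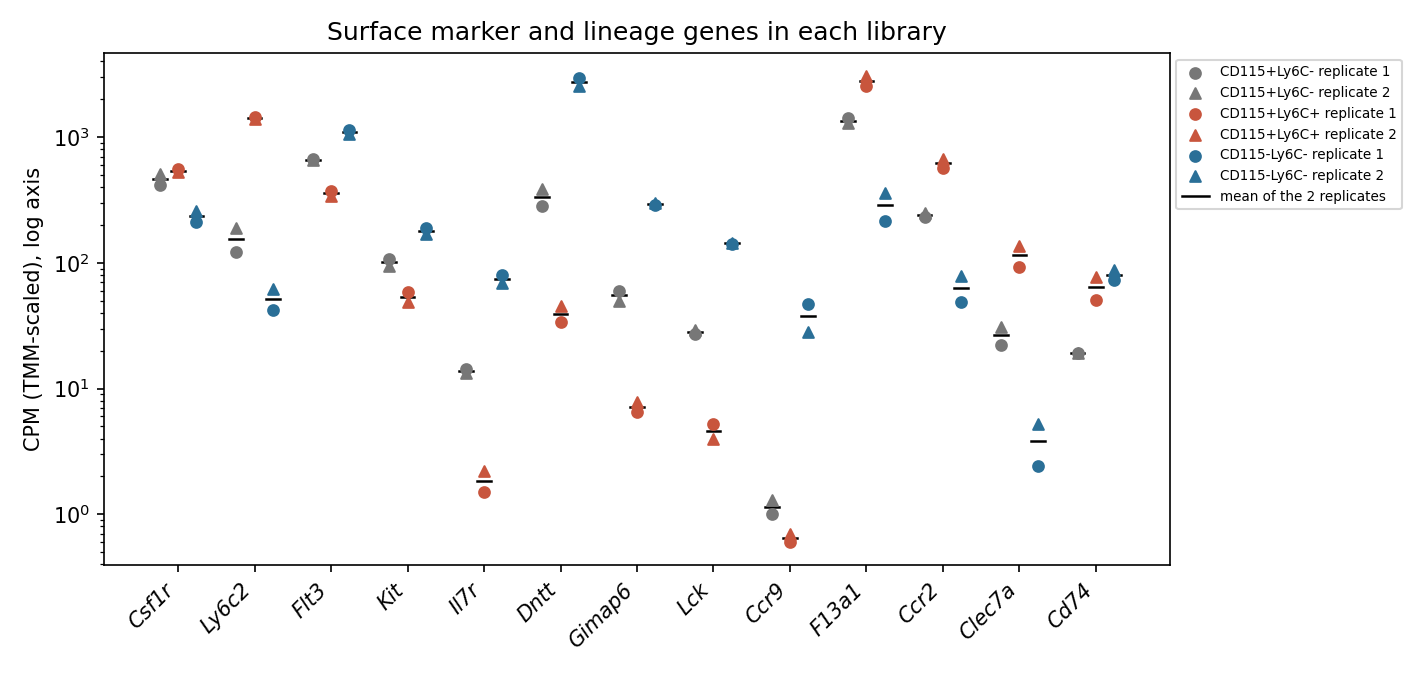
CPM (TMM-scaled, log axis) of marker and lineage genes in each of the 6 libraries, with color for the subset, shape for the replicate and a line at the mean of the 2 replicates. Ly6c2, F13a1, Ccr2 and Clec7a are highest in CD115+Ly6C+, and Flt3, Kit, Il7r, Dntt, Gimap6, Lck and Ccr9 in CD115-Ly6C-.

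The first comparison asked what parts CD115+ progenitors with and without Ly6C. CD115+Ly6C+ libraries held more transcripts of monocyte, macrophage and neutrophil granule genes than CD115+Ly6C- libraries, and fewer of early lymphoid, T cell and stem cell genes. These are calls of gene lists by camera with its preset correlation. With an estimated correlation, where the test has 3 residual degrees of freedom, 0 lists were called (smallest adjusted p = 0.124, with 8 at an unadjusted p under 0.05). Lgals3 (Entrez gene 16854, chromosome 14, 47373860 to 47386167), which encodes galectin-3, a lectin of macrophages, stood at 187 ± 16.7 against 18.7 ± 8.92 CPM (n = 2 each), a 10-fold difference. In the other direction Rag2 (Entrez gene 19374, chromosome 2, 101624712 to 101632528), part of the recombinase that assembles antigen receptor genes, stood at 1.31 ± 0.515 against 18.3 ± 5.78 CPM. Dntt (Entrez gene 21673, chromosome 19, 41029275 to 41059525), the polymerase that adds bases at the joints of those genes, was at 39.3 ± 8.15 against 333 ± 73.6 CPM, and Gimap6, a GTPase of lymphocytes, at 7.16 ± 0.974 against 55.1 ± 7.02 CPM. Of 12127 genes tested, 638 were higher and 526 lower in CD115+Ly6C+, of which 279 and 211 by at least 2-fold.

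The 10 largest log2 fold changes, from 3.10 to 3.62, belonged to Ceacam10, Fpr1, Lgals3, S100a9, Mmp9, Ly6c2, Mrgpra2b, Retnlg, S100a8 and Lrg1. Fpr1 encodes a formyl peptide receptor of phagocytes, Mmp9 a granule protease, and S100a8 and S100a9 the chains of calprotectin. Lgals3 and Ly6c2 kept edgeR adjusted p under the threshold whichever library was left out. S100a8 lost its call without CD115+Ly6C+ replicate 2 (0.0564), Fpr1, Mmp9 and Retnlg without either CD115+Ly6C+ library (0.0582 to 0.0914), and S100a9 and Lrg1 without CD115+Ly6C- replicate 1 or either CD115+Ly6C+ library (0.0614 to 0.133). Ceacam10 and Mrgpra2b lost theirs without any 1 library of CD115+Ly6C- or CD115+Ly6C+ (0.0525 to 0.205), and Mrgpra2b also with the replicate block (0.058) and the length trend removed (0.0556). The 10 smallest, from -3.81 to -2.36, belonged to Rag2, Gimap7, Dntt, Gimap6, Sstr2, Gimap1, Lck, Angpt1, Mctp2 and Blnk. Of these, Gimap7 lost its call without CD115+Ly6C- replicate 1 (edgeR adjusted p = 0.0518). Rag2 and Sstr2 overlap Iftap and Slc39a11, with which reads may be shared.

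Monocyte genes were higher in CD115+Ly6C+ in 12 of 24 tested members (19 adjusted over the list alone, where 1 was lower), with a median log2 fold change of 1.21 (camera adjusted p = 7.15e-17). After Ly6c2 these were led by S100a4, a calcium-binding protein, at 160.0 ± 28.3 against 21 ± 8.3 CPM, and Emilin2, a matrix glycoprotein, at 41.5 ± 1.36 against 15.4 ± 1.33 CPM. Fc gamma and C-type lectin receptor genes were higher in 11 of 17 members (16 adjusted over the list alone), with a median of 2.09 (camera adjusted p = 6.08e-17). Examples were Fcgr3, a low-affinity receptor for IgG, at 35.1 ± 6.71 against 6.6 ± 0.948 CPM, Clec5a at 32 ± 3.13 against 5.54 ± 1.46 CPM, and Cd209a, a relative of DC-SIGN, at 77.2 ± 24.6 against 13.1 ± 1.87 CPM. Of 12 macrophage genes, 6 were higher (7 adjusted over the list alone), led by Lgals3 (median 1.48, camera adjusted p = 4.97e-06). Monocyte, Fc receptor and macrophage genes had an adjusted p = 0.14, 0.129 and 0.14 with an estimated correlation.

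Neutrophil and granule genes were higher in 18 of 25 members and lower in 1 (22 and 1 adjusted over the list alone), with a median of 2.23 (camera adjusted p = 3.43e-18, and adjusted p = 0.14 with an estimated correlation). Hp, which encodes haptoglobin, stood at 67.6 ± 2.68 against 13.1 ± 4.02 CPM (n = 2 each). The proteases Prtn3 and Ctsg, made early in granule formation, stood at 562 ± 24.8 against 250.0 ± 24.3 CPM and 1119 ± 72.2 against 585 ± 23.5 CPM. Of the other early granule genes, Elane was higher too, at 82.4 and 127.4 against 28.0 and 45.1 CPM. Mpo overlapped between the subsets, at 3559 and 4158 against 4646 and 3682 CPM. Nkg7, the 1 member that was lower, is also a granule gene of cytotoxic lymphocytes and stood at 29.5 ± 5.86 against 60.1 ± 13.1 CPM. Its call was lost without CD115+Ly6C- replicate 1 (edgeR adjusted p = 0.0998) or CD115+Ly6C+ replicate 1 (0.0682). The 14 late granule genes of this list lay apart between the CD115+Ly6C- libraries, by a median log2 ratio of replicate 2 to replicate 1 of 2.01, against -0.04 in CD115+Ly6C+ and -1.05 in CD115-Ly6C-. S100a8 stood at 62.1 and 245.9 CPM in the CD115+Ly6C- libraries and at 1321 and 1328 CPM in those of CD115+Ly6C+. S100a8, S100a9, Mmp9 and Retnlg, among the largest changes above, are such late granule genes. Whether neutrophil-lineage cells or their RNA gave these transcripts in CD115+Ly6C+ was not tested.

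**Figure D3:**
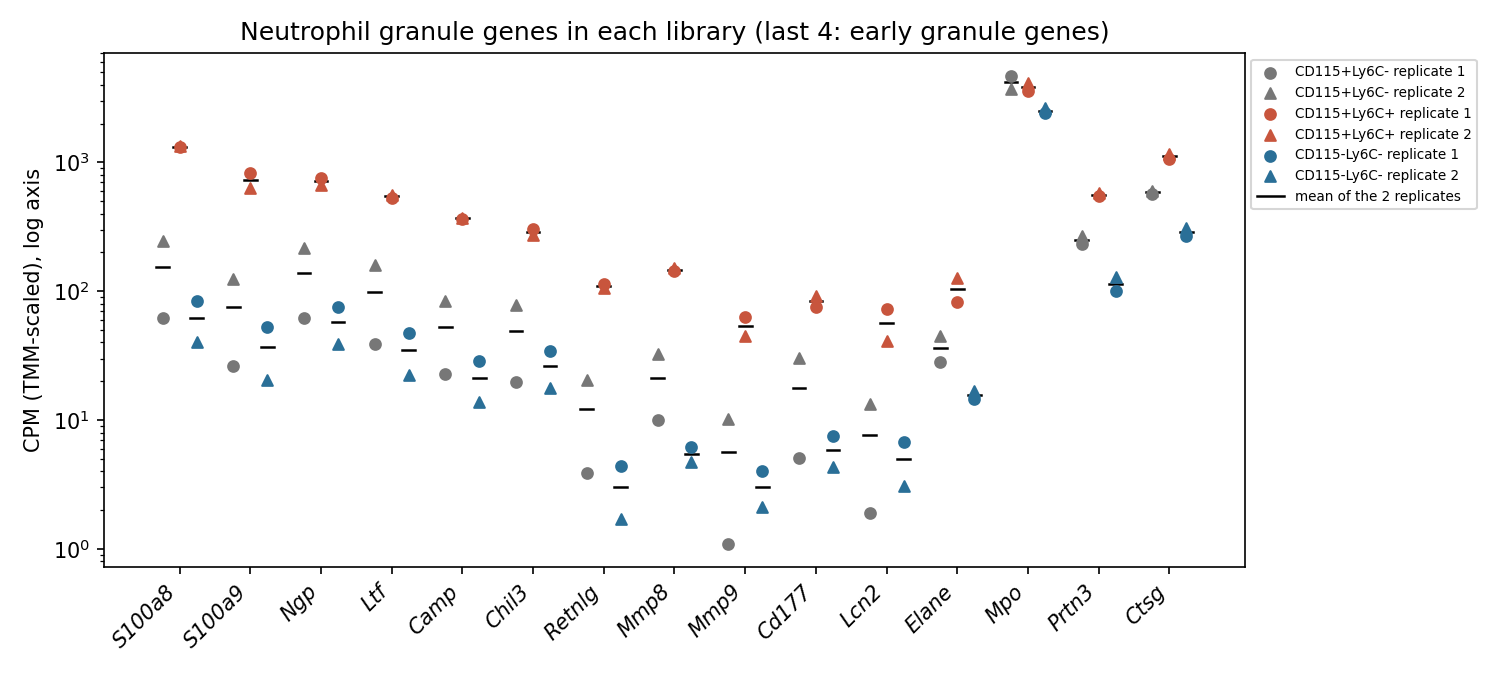
CPM (TMM-scaled, log axis) of late and, as the last 4, early neutrophil granule genes in each of the 6 libraries, with color for the subset, shape for the replicate and a line at the mean of the 2 replicates. For S100a8 the CD115+Ly6C- libraries lie at 62.1 and 245.9 CPM and those of CD115+Ly6C+ at 1321 and 1328.

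Antigen presentation genes of MHC class II were higher in CD115+Ly6C+ in 7 of 17 members and lower in 1 (9 and 1 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 5.93e-07). Ifi30, a thiol reductase that unfolds antigens, stood at 167 ± 16.4 against 43.7 ± 7.21 CPM, and the class II chain genes H2-Ab1 and H2-Eb1 at 42.4 ± 8.43 against 12.6 ± 0.1 CPM and 11.8 ± 0.464 against 2.32 ± 0.168 CPM. H2-Ob, a chain of the H2-O protein that restrains peptide loading, went the other way at 29.2 ± 1.75 against 73.9 ± 0.23 CPM (n = 2 each). Pan dendritic cell genes, which share class II genes with that list, were higher in 7 of 18 members and lower in 1 (9 and 1 adjusted over the list alone; median 0.36, camera adjusted p = 5.74e-05). For both lists adjusted p = 0.137 and 0.133 with an estimated correlation. Type 1 conventional dendritic cell genes were higher in 4 of 16 members (4 adjusted over the list alone, where 1 was lower), led by Naaa at 21.3 ± 0.911 against 5.2 ± 1.65 CPM and Clec9a, a receptor for dead cells, at 58.6 ± 1.45 against 29.8 ± 0.909 CPM. Clec9a overlaps Clec12b, with which reads may be shared. That list's median was 0.24 (camera adjusted p = 0.037, 0.368 with an estimated correlation, 0.0731 with fry, 0.0616 with no filter). Its call ended without CD115+Ly6C- replicate 1 or either library of CD115+Ly6C+ or CD115-Ly6C- (0.0611 to 0.28). Plasmacytoid dendritic cell genes went both ways, with 6 higher and 8 lower of 26 (7 and 9 adjusted over the list alone; median -0.26, camera adjusted p = 0.00846, 0.355 with an estimated correlation). The lower ones were led by Dntt, Ly6d and Blnk and the higher ones by Ly6c2, a gene of the sorted protein Ly6C. This call ended without CD115+Ly6C+ replicate 1 (0.0585), without CD115-Ly6C- replicate 2 (0.0568), with fry (0.0514) and with no filter on low counts (0.112).

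Early lymphoid genes were lower in CD115+Ly6C+ in 7 of 17 members and higher in 1 (9 and 2 adjusted over the list alone), with a median of -1.03 (camera adjusted p = 2.64e-13). Besides Dntt these were led by Ly6d, a marker of B lineage commitment, at 23.7 ± 1.4 against 83.8 ± 7.16 CPM and Arpp21 at 1.32 ± 0.26 against 10.5 ± 0.233 CPM. Cd52, which encodes a short surface glycoprotein of many leukocytes, was the 1 member higher in CD115+Ly6C+, at 253 ± 8.05 against 137 ± 9.71 CPM. T cell genes were lower in 5 of 8 members (6 adjusted over the list alone; median -1.20, camera adjusted p = 1.18e-08). Lck, a kinase of T cell receptor signaling, stood at 4.57 ± 0.872 against 28.1 ± 1.42 CPM, and Zap70, which acts next to it, at 1.5 ± 0.169 against 5.39 ± 1.24 CPM (n = 2 each). Zap70 lost its call without CD115+Ly6C+ replicate 2 (edgeR adjusted p = 0.0619). Stem and multipotent progenitor genes were lower in 10 of 24 members (11 adjusted over the list alone; median -0.80, -0.73 with members at 0 counts set to their bound, camera adjusted p = 1.49e-10). Angpt1, the Tie2 ligand, stood at 6.66 ± 0.745 against 36.4 ± 7.17 CPM, and the adhesion receptors Adgrl4 and Adgrg1 at 54 ± 0.644 against 107 ± 4.4 CPM and 62.5 ± 7.34 against 170.0 ± 22.2 CPM. Lymphoid, T cell and stem cell genes had an adjusted p = 0.124, 0.129 and 0.129 with an estimated correlation.

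Chemokine receptor genes were higher in 3 of 12 members and lower in 1 (4 and 1 adjusted over the list alone; median 0.40, camera adjusted p = 0.041, 0.368 with an estimated correlation). Ccr7, which guides cells to lymph nodes, stood at 18.3 ± 2.22 against 41.6 ± 3.32 CPM, and Cxcr2, a receptor of neutrophils, at 11.3 ± 1.31 against 1.11 ± 0.606 CPM. Toll-like receptor and adaptor genes were higher in 2 of 18 and lower in 1, the same counts as adjusted over the list alone (median 0.57, camera adjusted p = 0.0254, 0.424 with an estimated correlation). Tlr7, the sensor of single-stranded RNA, was lower in CD115+Ly6C+, at 3.39 ± 0.727 against 17.5 ± 0.177 CPM. Both list calls ended with fry (0.0839 each), without CD115+Ly6C- replicate 1 (0.107 and 0.23) and without CD115+Ly6C+ replicate 1 (0.0611 and 0.0539). Of 21 cytokine receptor and kinase genes, 6 were lower and 1 higher (6 and 2 adjusted over the list alone), led by Il7r and Il1r1, an interleukin 1 receptor, at 5.48 ± 0.213 against 22 ± 4.19 CPM. That list's test pointed down (camera adjusted p = 0.00763, 0.14 with an estimated correlation), as did its mean of -0.29, while its median was 0.03, or -0.04 with library totals. It passed no longer without CD115+Ly6C+ replicate 1 (0.0585). Megakaryocyte, basophil and mast cell genes were higher in 2 of 13 (4 adjusted over the list alone; median 0.97, camera adjusted p = 0.00846, 0.14 with an estimated correlation). The first of them, Pf4, rested on 1 count in CD115+Ly6C- and 70 in CD115+Ly6C+, a ratio of 76.6 (exact 95% counting interval 13.3 to 3070), and lost its call without either CD115+Ly6C- library or CD115+Ly6C+ replicate 2 (edgeR adjusted p = 0.0803 to 0.158).

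Ribosomal protein genes were called as a group (median 0.37, camera adjusted p = 1.49e-10, 0.511 with an estimated correlation, 0.171 with fry), with 3 of 80 members higher and 0 adjusted over the list alone by edgeR. At an unadjusted p under 0.05, 47 were higher and 0 lower. Short transcripts as a whole were higher in CD115+Ly6C+: log2 fold change correlated with gene length across genes (Spearman's rho -0.33), with a median of 0.22 in the shortest 25% of genes and -0.20 in the longest 25%. With each library's length trend removed, the ribosomal list had a camera adjusted p of 0.56. G2 and M phase genes were higher in 4 of 32 (6 adjusted over the list alone; median 0.13, camera adjusted p = 0.00961, 0.676 with an estimated correlation, 0.256 with fry), and not without CD115+Ly6C- replicate 2 (0.339). Birc5, or survivin, which acts in cell division, stood at 543 ± 59.2 against 340.0 ± 15.1 CPM, and lost its call with the length trend removed (edgeR adjusted p = 0.0757) and without CD115+Ly6C- replicate 1, CD115+Ly6C- replicate 2 or CD115+Ly6C+ replicate 2 (0.0803 to 0.0865).

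The camera test did not call the other lists in this comparison. Their adjusted p was 0.0604 for type 2 conventional dendritic cell genes, 0.134 for S phase genes, 0.134 for interferon stimulated genes and 0.18 for glycolysis genes. It was 0.611 for B cell genes, 0.859 for natural killer and innate lymphoid genes, 0.896 for erythroid genes, 0.854 for immediate early and stress genes, 0.991 for cholesterol synthesis genes, 0.896 for dendritic cell transcription factors and 0.85 for sort markers. Type 2 conventional dendritic cell genes passed with the replicate block (0.0343), library totals (0.047) and the length trend removed (0.0131), and without CD115+Ly6C+ replicate 2 (0.0371) or CD115-Ly6C- replicate 1 (0.00883) or 2 (0.0148). Immediate early genes passed without CD115+Ly6C- replicate 2 (0.0276), S phase genes with library totals (0.047) and no filter (0.0464), and glycolysis genes with fry (0.0402). For sort markers and B cell genes the median and mean were above 0 and the test pointed down. For immediate early and cholesterol genes the mean was below 0 and the test pointed up, and for transcription factors the mean was 0.16 and the test pointed down.

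In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1164 genes, 54.8% of them higher in CD115+Ly6C+, and camera called 17 of 28 lists, 12 up and 5 down. With library totals alone, 38.4% of 1262 genes were higher, and the median log2 fold change of all genes was -0.08 in place of -0.01. Leaving out a library of either subset lowered the count, to 220 or 501 without CD115+Ly6C- replicate 1 or 2 and to 441 or 291 without CD115+Ly6C+ replicate 1 or 2. It was 1810 with no filter on low counts, 711 with the length trend removed and 217 for a fold of at least 1.5. With an estimated correlation camera called 0 lists (smallest adjusted p = 0.124; 8 at an unadjusted p under 0.05), and fry called 12.

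The next comparison set progenitors without CD115 against CD115+ progenitors, both without Ly6C. CD115-Ly6C- cells carried more transcripts of early lymphoid, stem cell, T cell, B cell and interferon stimulated genes, and fewer of genes of cell division and of monocytes. Of these list calls by camera, with an estimated correlation that of early lymphoid genes held (adjusted p = 0.0458) and the others did not (0.0896 to 0.244). Ccr9 (Entrez gene 12769, chromosome 9, 123767211 to 123783457), a chemokine receptor of plasmacytoid dendritic cells and thymus-seeding progenitors, stood at 37.5 ± 13 against 1.19 ± 0.196 CPM (n = 2 each), a 31.4-fold difference. Dntt stood at 2738 ± 279 against 333 ± 73.6 CPM, an 8.21-fold difference. Lower in CD115-Ly6C- were Clec7a (Entrez gene 56644, chromosome 6, 129461591 to 129472785), the receptor dectin-1 for fungal glucans, at 3.79 ± 2.02 against 26.6 ± 6.26 CPM, and F13a1 (Entrez gene 74145, chromosome 13, 36867178 to 37050244), the A chain of clotting factor XIII made by monocytes, at 286 ± 101 against 1355 ± 85.4 CPM. Of the genes tested, 1022 were higher and 822 lower in CD115-Ly6C-, of which 621 and 154 by at least 2-fold.

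The 10 largest log2 fold changes, from 3.99 to 4.97, belonged to Ccr9, Gfra1, Mycn, Tmem254b, Lax1, Il17re, Tmem121, Tnni1, Wfdc18 and Myl10. Gfra1 encodes a receptor for glial cell line-derived neurotrophic factor, Mycn a transcription factor of the Myc family, and Lax1 an adaptor of lymphocyte receptor signaling. Mycn stood at 17.6 ± 4.28 against 0.659 ± 0.032 CPM and Lax1 at 40.3 ± 7.4 against 2.01 ± 0.986 CPM. Tnni1 and Wfdc18 lost their calls without CD115+Ly6C- replicate 1 (edgeR adjusted p = 0.0597 and 0.0651) or CD115-Ly6C- replicate 1 (0.0895 and 0.0687). The 10 smallest, from -2.81 to -1.84, belonged to Clec7a, F13a1, Clec9a, Cd209a, Mefv, Igsf6, Mmp8, Ifitm6, Ccr2 and Nostrin. Clec9a stood at 6.81 ± 0.126 against 29.8 ± 0.909 CPM, and Mefv, which encodes pyrin, at 4.45 ± 1.52 against 18.3 ± 0.0343 CPM. Mmp8 lost its call without CD115-Ly6C- replicate 1 (0.0713) or 2 (0.0795), and Nostrin without CD115+Ly6C- replicate 1 (0.0649). Gfra1, Clec9a and Igsf6 overlap other genes (Gm46650, Clec12b and Mettl9), with which reads may be shared.

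Early lymphoid genes were higher in CD115-Ly6C- in 13 of 17 members (15 adjusted over the list alone), with a median of 2.05 (camera adjusted p = 1.21e-28). This list was the only 1 of 28 that also passed with an estimated correlation (adjusted p = 0.0458). Besides Dntt its leading members were Ly6d at 316 ± 30.6 against 83.8 ± 7.16 CPM and Arpp21 at 54 ± 1.96 against 10.5 ± 0.233 CPM. T cell genes were higher in 6 of 8 members (7 adjusted over the list alone; median 1.85, camera adjusted p = 3.54e-12), led by Lck at 142 ± 1.22 against 28.1 ± 1.42 CPM, Cd6 at 24.6 ± 1.92 against 4.91 ± 0.185 CPM and the adaptor Lat at 18.9 ± 2.73 against 3.56 ± 0.0834 CPM. B cell genes were higher in 6 of 14 members (8 adjusted over the list alone; median 1.88, camera adjusted p = 1.62e-06). Blk, a kinase of B cells, stood at 22.1 ± 2.02 against 2.43 ± 0.094 CPM, Cd72 at 124 ± 7.32 against 66 ± 7.94 CPM and Cd79a, a chain of the B cell receptor, at 12.5 ± 1.87 against 0.874 ± 0.94 CPM (n = 2 each). Cd72 overlaps Tesk1, with which reads may be shared. Natural killer and innate lymphoid genes were higher in 6 of 10 and lower in 1 (7 and 1 adjusted over the list alone; median 2.06, camera adjusted p = 3.64e-05). Gata3, a transcription factor of T and innate lymphoid cells, stood at 8.57 ± 2.02 against 0.184 ± 0.0358 CPM, and the killer receptor gene Klrk1, the 1 lower member, at 23.5 ± 1.97 against 49.3 ± 0.0902 CPM. Tcf7, which overlaps Skp1, had 268 counts in CD115-Ly6C- and 1 in CD115+Ly6C-, a ratio of 254 (exact 95% counting interval 45.2 to 10100). T cell, B cell and natural killer genes had an adjusted p = 0.0896, 0.091 and 0.107 with an estimated correlation.

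Stem and multipotent progenitor genes were higher in 14 of 24 members (18 adjusted over the list alone; median 1.13, camera adjusted p = 3.59e-13, 0.0896 with an estimated correlation). Adgrl4 stood at 233 ± 6.73 against 107 ± 4.4 CPM, Adgrg1 at 469 ± 79.9 against 170.0 ± 22.2 CPM and Meis1, a transcription factor of stem cells, at 64.7 ± 0.222 against 25.4 ± 4.31 CPM. Interferon stimulated genes were higher in 19 of 40 (24 adjusted over the list alone, where 1 was lower; median 0.72, camera adjusted p = 4.86e-12, 0.107 with an estimated correlation). They were led by Rtp4 at 36.9 ± 1.37 against 4.46 ± 0.524 CPM, Ifi44 at 58.8 ± 2.84 against 12.7 ± 1.03 CPM and Oasl2 at 33.2 ± 4.62 against 6.14 ± 0.287 CPM (n = 2 each), of which Rtp4 overlaps Masp1. Plasmacytoid dendritic cell genes were higher in 14 of 26 and lower in 3 (15 and 3 adjusted over the list alone; median 0.98, camera adjusted p = 1.05e-09, 0.107 with an estimated correlation). Their leading members were Ly6d, Dntt and Ccr9, of which the first and second are also on the early lymphoid list, and Ly6c2 was lower.

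MHC class II genes were higher in CD115-Ly6C- in 6 of 17 members and lower in 2 (7 and 4 adjusted over the list alone; median 0.58, camera adjusted p = 0.00362). H2-Ob stood at 302 ± 6.82 against 73.9 ± 0.23 CPM, Cd74, the invariant chain, at 80.6 ± 9.93 against 19.1 ± 0.115 CPM, and Ifi30, which was lower, at 20.7 ± 1.82 against 43.7 ± 7.21 CPM. Pan dendritic cell genes were higher in 5 of 18, the same count as adjusted over the list alone, with Cd74 and H2-Aa leading (median 0.36, camera adjusted p = 0.0099). With no filter on low counts, the calls of both lists ended (0.0977 and 0.0598), and with an estimated correlation their adjusted p was 0.2 and 0.187. Cytokine receptor and kinase genes were higher in 9 of 21 and lower in 3 (10 and 3 adjusted over the list alone; median 0.33, camera adjusted p = 0.00386, 0.149 with an estimated correlation). Il7r was joined by Il1r1 at 79.2 ± 4.81 against 22 ± 4.19 CPM, with Csf1r among the lower members. Dendritic cell transcription factors were higher in 8 of 32 and lower in 2 (11 and 2 adjusted over the list alone; median 0.34, camera adjusted p = 0.0174, 0.431 with an estimated correlation, 0.0571 with fry). Nfil3 stood at 137 ± 2.18 against 50.6 ± 2.61 CPM and Spib, a factor of plasmacytoid dendritic cells, at 14.6 ± 0.578 against 2.75 ± 1.51 CPM, though Spib lost its call without CD115+Ly6C- replicate 1 (edgeR adjusted p = 0.0736).

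G2 and M phase genes were lower in CD115-Ly6C- in 31 of 32 members, the same count as adjusted over the list alone (median -1.04, camera adjusted p = 5.23e-38, 0.122 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, stood at 149 ± 19.1 against 353 ± 26.3 CPM, Ube2c, an enzyme that works with that complex, at 79.2 ± 12 against 193 ± 5.54 CPM, and Nusap1, a spindle protein, at 154 ± 20.4 against 342 ± 19.3 CPM (n = 2 each). Cdc20 and Nusap1 overlap Elovl1 and Oip5. S phase genes were lower in 12 of 32 (16 adjusted over the list alone; median -0.34, camera adjusted p = 2.74e-07, 0.269 with an estimated correlation). Rrm1, a subunit of ribonucleotide reductase, stood at 794 ± 53 against 1207 ± 44.1 CPM and Tyms, thymidylate synthase, at 127 ± 8.42 against 186 ± 4.11 CPM. Both lost their calls without CD115+Ly6C- replicate 1 (edgeR adjusted p = 0.0567 and 0.0785) or CD115-Ly6C- replicate 1 (0.0779 and 0.121).

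Fc gamma and C-type lectin receptor genes were lower in CD115-Ly6C- in 9 of 17 members, the same count as adjusted over the list alone (median -1.22, -1.12 at the bound, camera adjusted p = 8.32e-10). Monocyte genes were lower in 9 of 24 and higher in 1 (13 and 1 adjusted over the list alone; median -0.89, camera adjusted p = 1.65e-08, 0.0571 with fry). F13a1 was followed by Ccr2, the receptor that draws monocytes from the marrow, at 63.5 ± 20.3 against 239 ± 12.4 CPM, and Ms4a6c at 202 ± 37.9 against 486 ± 26.3 CPM. Csf3r, the receptor for granulocyte colony-stimulating factor, was the 1 higher member, at 61.8 ± 5.49 against 31.2 ± 1.56 CPM (n = 2 each). Neutrophil and granule genes were lower in 6 of 25 and higher in 1 (9 and 1 adjusted over the list alone; median -1.09, camera adjusted p = 7.59e-06, 0.161 with fry). Ap3s1, which overlaps Atg12, stood at 84.6 ± 6.39 against 180.0 ± 0.093 CPM and Ctsg at 289 ± 29.9 against 585 ± 23.5 CPM, while Nkg7 was higher in CD115-Ly6C-, at 138 ± 5.08 against 60.1 ± 13.1 CPM. Late granule genes of this list differed between the libraries of a subset by a median log2 ratio of 2.01 in CD115+Ly6C- and -1.05 in CD115-Ly6C-. S100a8 stood at 62.1 CPM in CD115+Ly6C- replicate 1 and at 84.2 and 40.7 CPM in the CD115-Ly6C- libraries. For Ngp the values were 61.7, 75.5 and 39.1 CPM. In that replicate Mmp8 and Hp were above both CD115-Ly6C- libraries, and Lcn2 and Mmp9 below both. The late granule difference thus rested mainly on CD115+Ly6C- replicate 2. Fc receptor, monocyte and neutrophil genes had an adjusted p = 0.146, 0.244 and 0.337 with an estimated correlation.

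Megakaryocyte, basophil and mast cell genes were higher in 4 of 13 and erythroid genes in 3 of 12, the same counts as adjusted over each list alone (median 1.1 and 0.51, camera adjusted p = 0.00768 and 0.0252). Cpa3, a protease of mast cells and their progenitors, stood at 29.1 ± 4.3 against 1.93 ± 0.0527 CPM, and Car2, a carbonic anhydrase of red cell precursors, at 94 ± 6.38 against 27.5 ± 7.43 CPM. The first list's call ended without CD115-Ly6C- replicate 2 (0.0542) and with no filter (0.0598). The second's ended without CD115+Ly6C- replicate 2 (0.187), without CD115-Ly6C- replicate 1 (0.0904), with fry (0.0894), with no filter (0.0814) and with library totals (0.0606). Immediate early and stress genes were higher in 3 of 28 (7 adjusted over the list alone, where 2 were lower; median 0.71, camera adjusted p = 0.0162), led by Dusp2, a phosphatase of kinase signaling, at 138 ± 4.05 against 44 ± 23.4 CPM. That call ended with fry (0.32), without CD115+Ly6C- replicate 1 (0.16) and without CD115-Ly6C- replicate 2 (0.408). These genes also lay apart between the libraries of each subset, by a median log2 ratio of replicate 2 to replicate 1 of 1.1 in CD115+Ly6C-, 0.52 in CD115+Ly6C+ and 0.66 in CD115-Ly6C-. With a replicate block, which takes off such a shift, the list was called up (camera adjusted p = 4.13e-08), though no label pairs the replicates. In the order given, the 3 lists had an adjusted p = 0.149, 0.431 and 0.638 with an estimated correlation.

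Lists not called had a camera adjusted p of 0.0816 for sort markers, 0.199 for type 1 conventional dendritic cell genes, 0.168 for type 2 conventional dendritic cell genes and 0.168 for macrophage genes. It was 0.838 for Toll-like receptor and adaptor genes, 0.439 for chemokine receptor genes, 0.705 for glycolysis genes, 0.979 for cholesterol synthesis genes and 0.899 for ribosomal protein genes. Ribosomal protein genes had a median of 0.02 here, and with the length trend removed they were called up (0.0069). Without CD115+Ly6C- replicate 1 the macrophage list (0.0206) and the ribosomal list (0.0203, down) were called. Log2 fold change rose with gene length across genes (Spearman's rho 0.18). For ribosomal and cholesterol genes the median and mean lay above 0 and the test pointed down, as it did for glycolysis genes, where the mean was 0.04 and the median -0.06.

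In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1844 genes, 55.4% of them higher in CD115-Ly6C-, and camera called 19 of 28 lists, 14 up and 5 down. With library totals alone, 74.3% of 1862 genes were higher, with a median log2 fold change over all genes of 0.14 in place of 0.02. On log2(FPKM + 1), 70.3% of 1934 were. The count fell to 498 or 965 without CD115+Ly6C- replicate 1 or 2, to 485 or 1219 without CD115-Ly6C- replicate 1 or 2, and to 357 for a fold of at least 1.5. With an estimated correlation 1 list was called, and with fry 14.

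The last comparison set the subsets that differed in both markers against each other, CD115-Ly6C- against CD115+Ly6C+, and held the most differences. Lymphoid, stem cell and plasmacytoid dendritic cell genes were higher in CD115-Ly6C-, and monocyte, macrophage, neutrophil, Fc receptor and cell division genes in CD115+Ly6C+. These are again calls of lists by camera, and 0 of them held with an estimated correlation (smallest adjusted p = 0.0856; 8 lists at an unadjusted p under 0.05). Dntt stood at 2738 ± 279 against 39.3 ± 8.15 CPM (n = 2 each), a 69.7-fold difference, and Tox (Entrez gene 252838, chromosome 4, 6686353 to 6991557), a transcription factor of T and innate lymphoid cells, at 48.5 ± 9.59 against 0.411 ± 0.266 CPM. Clec7a stood at 3.79 ± 2.02 against 115 ± 31.3 CPM and F13a1 at 286 ± 101 against 2795 ± 354 CPM. Of the genes tested, 2435 were higher and 2333 lower in CD115-Ly6C-, of which 1248 and 718 by at least 2-fold and 371 and 163 by at least 8-fold.

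The 10 largest log2 fold changes belonged to Gfra1, Tmem121, Myl10, Cd247, Tox, Ctla2b, Dntt, Lax1, St6gal1 and Ccr9. For 5 of them CD115+Ly6C+ had 1 to 3 counts. Their ratios were 242 (exact 95% counting interval 82.6 to 1180) for Gfra1, 195 (exact 95% counting interval 66.5 to 949) for Tmem121 and 222 (exact 95% counting interval 39.5 to 8800) for Myl10. Cd247, the zeta chain of the T cell receptor complex, which overlaps Pou2f1, had a ratio of 198 (exact 95% counting interval 54.6 to 1640), and Ctla2b of 83.2 (exact 95% counting interval 28.2 to 406). The log2 fold changes of the other 5 lay between 5.87 for Ccr9 and 6.88 for Tox. The 10 smallest, from -6.10 to -4.74, belonged to Fpr1, Ceacam10, Chil1, Ly6g, Retnlg, Clec7a, Lrg1, Lgals3, Ly6c2 and Mmp8. All 20 kept edgeR adjusted p under the threshold in each of the 6 fits without 1 library, and Ly6g did not with DESeq2 (0.0621).

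Early lymphoid genes were higher in CD115-Ly6C- in 13 of 17 members and lower in 1, T cell genes higher in 7 of 8, and both had the same counts adjusted over the list alone. Their medians were 4.64 and 3.29 (camera adjusted p = 1.20e-25 and 1.89e-13). Besides Ly6d and Dntt, Arpp21 stood at 54 ± 1.96 against 1.32 ± 0.26 CPM, Lck at 142 ± 1.22 against 4.57 ± 0.872 CPM, and Cd52, the early lymphoid member that was lower, at 144 ± 8.09 against 253 ± 8.05 CPM. Cd52 lost its call with the length trend removed (edgeR adjusted p = 0.202). Stem and multipotent progenitor genes were higher in 19 of 24 (20 adjusted over the list alone; median 1.84, camera adjusted p = 7.77e-17), with Adgrl4 at 233 ± 6.73 against 54 ± 0.644 CPM and Angpt1 at 98.3 ± 11.8 against 6.66 ± 0.745 CPM (n = 2 each). B cell genes were higher in 6 of 14 and lower in 1, the same counts as adjusted over the list alone (median 1.43, camera adjusted p = 6.49e-04), with Cd72 at 124 ± 7.32 against 15.3 ± 0.692 CPM and Blk at 22.1 ± 2.02 against 1.09 ± 0.108 CPM. Natural killer and innate lymphoid genes were higher in 8 of 10 and lower in 1 (8 and 2 adjusted over the list alone; median 3.49, camera adjusted p = 0.00506), led by Il18r1, an interleukin 18 receptor chain, at 11.7 ± 1.19 against 0.64 ± 0.196 CPM. In the order given, the 5 lists had with an estimated correlation an adjusted p = 0.0856, 0.0942, 0.0942, 0.159 and 0.159.

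Plasmacytoid dendritic cell genes were higher in 15 of 26 and lower in 6, the same counts as adjusted over the list alone (median 1.28, camera adjusted p = 2.08e-07). Blnk, an adaptor of B cell receptor signaling, stood at 74.4 ± 8.88 against 4.84 ± 0.612 CPM and Ly6d at 316 ± 30.6 against 23.7 ± 1.4 CPM. Ly6d and Dntt are also on the early lymphoid list, so the calls of these lists are not separate, and Ly6c2 was among the lower members. Interferon stimulated genes were higher in 20 of 40 and lower in 7 (23 and 7 adjusted over the list alone; median 0.63, camera adjusted p = 6.49e-04), with Ifi44 at 58.8 ± 2.84 against 8.12 ± 0.733 CPM and Rtp4 at 36.9 ± 1.37 against 2.87 ± 0.594 CPM. Cmpk2 was among those lower in CD115-Ly6C-, at 49.3 ± 5.12 against 107 ± 6.79 CPM (n = 2 each). Cytokine receptor and kinase genes were higher in 10 of 21 and lower in 5 (10 and 7 adjusted over the list alone; median 0.24, camera adjusted p = 0.001), with Il1r1 at 79.2 ± 4.81 against 5.48 ± 0.213 CPM. Plasmacytoid, interferon and cytokine receptor genes had an adjusted p = 0.159, 0.277 and 0.159 with an estimated correlation.

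On the myeloid side, Fc gamma and C-type lectin receptor genes were lower in CD115-Ly6C- in 16 of 17 members (17 adjusted over the list alone; median -3.53, camera adjusted p = 1.88e-17). After Clec9a, Cd209a stood at 3.05 ± 0.542 against 77.2 ± 24.6 CPM and Clec5a at 1.9 ± 0.126 against 32 ± 3.13 CPM (n = 2 each). Monocyte genes were lower in 21 of 24 and higher in 3, neutrophil and granule genes lower in 23 of 25 and higher in 1, and macrophage genes lower in 7 of 12, with the same counts adjusted over each list alone. Medians were -2.25, -3.47 and -1.83 (camera adjusted p = 7.77e-17, 7.94e-15 and 7.07e-04). Ccr2 stood at 63.5 ± 20.3 against 619 ± 73.5 CPM, Ap3s1, which overlaps Atg12, at 84.6 ± 6.39 against 323 ± 12.6 CPM, Ctsg at 289 ± 29.9 against 1119 ± 72.2 CPM and Adgre1, which encodes F4/80, at 1.25 ± 0.131 against 10.3 ± 1.58 CPM. Csf3r and Nkg7 were higher in CD115-Ly6C-, at 61.8 ± 5.49 against 31.8 ± 3.62 CPM and 138 ± 5.08 against 29.5 ± 5.86 CPM. The late granule genes again lay apart between the CD115-Ly6C- libraries (median log2 ratio -1.05) and not between those of CD115+Ly6C+ (-0.04). Fc receptor, monocyte, neutrophil and macrophage genes had an adjusted p = 0.152, 0.159, 0.182 and 0.277 with an estimated correlation.

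G2 and M phase genes were lower in CD115-Ly6C- in 31 of 32 members, the same count as adjusted over the list alone (median -1.08, camera adjusted p = 8.27e-24, 0.17 with an estimated correlation). Birc5 stood at 157 ± 15.9 against 543 ± 59.2 CPM and Cdk1, the kinase that starts mitosis, at 127 ± 8.35 against 340.0 ± 4.89 CPM (n = 2 each). S phase genes were lower in 15 of 32 and higher in 5 (16 and 6 adjusted over the list alone; median -0.34, camera adjusted p = 0.0226, 0.694 with an estimated correlation). Tyms stood at 127 ± 8.42 against 267 ± 12.4 CPM, and Ung, which was higher in CD115-Ly6C- and overlaps Alkbh2, at 106 ± 0.0378 against 71.3 ± 3.44 CPM. That list's call ended without CD115-Ly6C- replicate 1 (0.0924) and with library totals (0.0992). Ribosomal protein genes were lower in 24 of 80 (18 adjusted over the list alone; median -0.35, camera adjusted p = 1.50e-04, 0.694 with an estimated correlation, 0.186 with fry). Here too fold changes followed length across genes (Spearman's rho 0.33), with a median of -0.34 in the shortest 25% of genes and 0.31 in the longest 25%. Without that trend the ribosomal list pointed up and was not called (camera adjusted p = 0.174).

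Apart from the plasmacytoid list, dendritic cell lists did not pass here. Camera adjusted p was 0.746 for type 1 conventional dendritic cell genes, 0.887 for type 2 conventional dendritic cell genes, 0.551 for pan dendritic cell genes, 0.377 for antigen presentation by MHC class II and 0.121 for dendritic cell transcription factors. Single members moved far in both directions: H2-Ob stood at 302 ± 6.82 against 29.2 ± 1.75 CPM and Ifi30 at 20.7 ± 1.82 against 167 ± 16.4 CPM, Clec9a at 6.81 ± 0.126 against 58.6 ± 1.45 CPM and Nfil3 at 137 ± 2.18 against 40.0 ± 4.84 CPM. For the remaining lists it was 0.236 for sort markers, 0.244 for erythroid genes, 0.873 for megakaryocyte, basophil and mast cell genes and 0.211 for immediate early and stress genes. It was 0.266 for Toll-like receptor and adaptor genes, 0.551 for chemokine receptor genes, 0.312 for glycolysis genes and 0.997 for cholesterol synthesis genes. Tlr7 stood at 44.5 ± 2.58 against 3.39 ± 0.727 CPM (n = 2 each). Fry called the sort markers (0.0416), glycolysis genes (0.0297) and transcription factors (0.0453), and immediate early genes passed with the replicate block (4.88e-04) and without CD115+Ly6C- replicate 1 (0.049), CD115+Ly6C+ replicate 2 (0.0184) or CD115-Ly6C- replicate 1 (0.00283). Transcription factors also passed with no filter (0.0493) and without CD115+Ly6C+ replicate 1 (0.0301), and Toll-like receptor genes with no filter (0.0463). The median and the test differed in sign for type 2 conventional dendritic cell, erythroid, and megakaryocyte, basophil and mast cell genes (0.15, -0.16 and -0.34). The mean and the test did for the first and last of these (0.19 and -0.23), and for sort markers, chemokine receptor and cholesterol genes (-0.03, 0.04 and 0.05).

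In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4768 genes, 51.1% of them higher in CD115-Ly6C-, and camera called 15 of 28 lists, 8 up and 7 down. With library totals alone, 69.8% of 5022 genes were higher, with a median log2 fold change over all genes of 0.22 in place of 0.03, and on log2(FPKM + 1) 66.4% of 4859 were. The count was 2983 without CD115+Ly6C+ replicate 2, 2989 without CD115-Ly6C- replicate 1 and 1665 for a fold of at least 1.5. With an estimated correlation camera called 0 lists (smallest adjusted p = 0.0856; 8 at an unadjusted p under 0.05), and fry called 17.

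**Figure D4:**
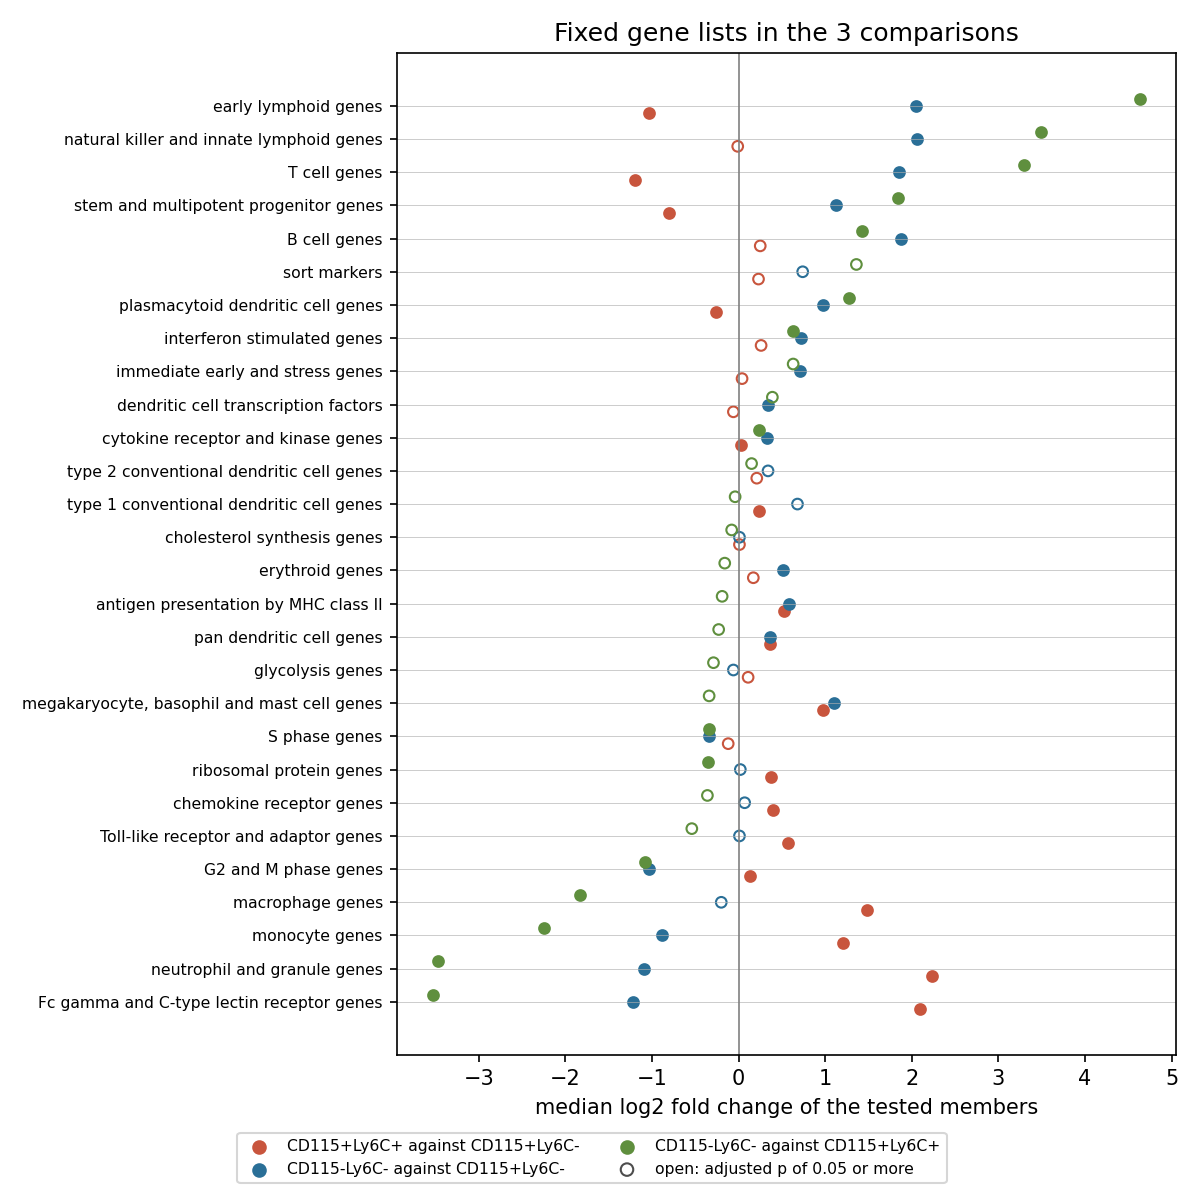
Median log2 fold change of the tested members of each gene list (1 line per list) in the 3 comparisons, by color, with filled points where the camera adjusted p was under 0.05. Early lymphoid genes had medians of -1.03, 2.05 and 4.64, and neutrophil and granule genes of 2.23, -1.09 and -3.47, for CD115+Ly6C+ against CD115+Ly6C-, CD115-Ly6C- against CD115+Ly6C- and CD115-Ly6C- against CD115+Ly6C+.

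Genes that set 1 subset apart from both others were counted at 2-fold or more. CD115-Ly6C- had 521 such genes higher and 143 lower, CD115+Ly6C+ 223 higher and 203 lower, and CD115+Ly6C- 24 lower. Independent lists of the same sizes would share 63.9, 9.1, 16.5, 21.7 and 14.3 genes. Unchanged genes gave a mean of 0.15 to 0.2 per subset and at most 1 in 20 simulated draws. As no gene differed in those draws, few could be called, so they do not measure chance overlap among this many calls. The comparisons of a subset share its libraries, so they were also split, with 1 library for each comparison. This gave 347 or 239 genes higher and 151 or 63 lower in CD115-Ly6C- (independent lists 36.5 or 23.1 and 10.7 or 3.7), and 90 or 114 higher and 109 or 137 lower in CD115+Ly6C+ (5.7 or 6.4 and 11 or 11.6). For CD115+Ly6C- it gave 8 or 5 lower, against 3.5 or 3 for independent lists. Those higher in CD115-Ly6C- were led by Ccr9, Gfra1 and Mycn, and those lower there by Clec7a, F13a1 and Clec9a. Ccr9 stood at 1.19 ± 0.196 CPM in CD115+Ly6C-, 0.636 ± 0.0321 in CD115+Ly6C+ and 37.5 ± 13 in CD115-Ly6C- (n = 2 each). Clec7a stood at 26.6 ± 6.26 CPM in CD115+Ly6C-, 115 ± 31.3 in CD115+Ly6C+ and 3.79 ± 2.02 in CD115-Ly6C-. Those higher in CD115+Ly6C+ were led by Ceacam10, Fpr1 and Lgals3, and those lower there by Rag2, Gimap7 and Dntt, with Fpr1 at 1.03 ± 1.09 CPM in CD115+Ly6C-, 10.7 ± 0.683 in CD115+Ly6C+ and 0.15 ± 0.00121 in CD115-Ly6C-. The rule does not ask that the other subsets be alike, so a graded gene can enter more than 1 set. Dntt, at 39.3 CPM in CD115+Ly6C+, 333 in CD115+Ly6C- and 2738 in CD115-Ly6C-, was also among the genes higher in CD115-Ly6C-. The CD115+Ly6C+ counts fell to 75 higher and 90 lower without CD115+Ly6C- replicate 1, 148 and 135 without CD115+Ly6C- replicate 2, 121 and 155 without CD115+Ly6C+ replicate 1, and 92 and 114 without CD115+Ly6C+ replicate 2. The CD115-Ly6C- counts fell to 235 higher without CD115+Ly6C- replicate 1, and to 244 higher and 64 lower without CD115-Ly6C- replicate 1.

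By edgeR's quasi-likelihood test 0 genes were higher in CD115+Ly6C- than in both other subsets at 2-fold or more, where independent lists would share 2.7. At any fold there were 6, at an unadjusted p under 0.05 and 2-fold there were 4, and DESeq2 gave 1. The 24 genes lower in CD115+Ly6C- were led by genes of MHC class II. H2-Eb1 stood at 2.32 ± 0.168 CPM in CD115+Ly6C-, 11.8 ± 0.464 in CD115+Ly6C+ and 9.06 ± 1.63 in CD115-Ly6C-. Cd74 stood at 19.1 ± 0.115 CPM in CD115+Ly6C-, 64 ± 18.4 in CD115+Ly6C+ and 80.6 ± 9.93 in CD115-Ly6C-, and H2-Aa at 5.7 ± 0.568 CPM in CD115+Ly6C-, 17.3 ± 0.222 in CD115+Ly6C+ and 18.5 ± 2.96 in CD115-Ly6C- (n = 2 each). Next came Pink1, a kinase of mitochondrial quality control, at 23.7 ± 0.967 CPM in CD115+Ly6C- and 70.4 ± 0.084 and 70.5 ± 51.2 in the others, and Ypel3. Both lost calls in most fits without 1 library (edgeR adjusted p = 0.0502 to 0.258). The count of 24 became 4 or 15 without CD115+Ly6C- replicate 1 or 2, 11 or 8 without CD115+Ly6C+ replicate 1 or 2, and 13 or 37 without CD115-Ly6C- replicate 1 or 2. It was 12 with the length trend removed and 45 with no filter on low counts.

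In both comparisons against CD115+Ly6C-, 441 genes were called, and 401 of them (90.9%) went in opposite directions. Of these 178 were higher in CD115+Ly6C+ and lower in CD115-Ly6C-, where independent lists would share 43.2, and 223 lower in CD115+Ly6C+ and higher in CD115-Ly6C-, against 44.3. Another 34 were higher in both (53.8 for independent lists) and 6 lower in both (35.7). Unchanged genes gave a mean of 0.2 calls in the same direction and 0 in opposite directions over 20 draws. No gene differed in those draws, so few calls could arise at the adjusted threshold. At an unadjusted p under 0.05 the unchanged genes gave 124.05 and 1.75. Because both comparisons share the CD115+Ly6C- libraries, chance favors the same direction. With the CD115+Ly6C- libraries split between the comparisons, 151 of 161 or 109 of 116 genes went in opposite directions (93.8% or 94%).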

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

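The alternatives were planned except library totals for the lists, removal of each library's length trend and the split of shared libraries, which were added after seeing the data. For each value below the cause was not tested, except where the setting itself asks for a larger or smaller fold.

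Numbers of genes differing are given for CD115+Ly6C+ against CD115+Ly6C-, CD115-Ly6C- against CD115+Ly6C- and CD115-Ly6C- against CD115+Ly6C+ in that order (1164, 1844 and 4768). A fold of at least 1.5 by glmTreat left 217, 357 and 1665. With no filter on low counts the first was 1810, with limma on log2(FPKM + 1) and no filter 415, and with the length trend removed 711. Leaving out 1 library gave 220 to 1139, 485 to 1744 and 2983 to 4632, where the lone sample of a subset was assumed to vary like the other subsets. All other settings stayed within 1.5-fold. The labels do not say that replicate numbers pair the samples, and over all genes the correlation of libraries with the same number was -0.004, -0.01 and 0.152 after the subset means were removed. Immediate early genes were an exception, higher in replicate 2 in each subset (24, 24 and 25 of 28 genes), so shared handling of some replicates stays open. A fit with a replicate block called 965, 1503 and 4550 genes, of which 891, 1435 and 4416 were also called without it.

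Lists called numbered 17, 19 and 15, and with an estimated correlation 0, 1 and 0 by camera (8, 9 and 8 at an unadjusted p under 0.05, and 12, 14 and 17 called by fry). Lists with no positive estimated correlation lost calls too. For CD115-Ly6C- against CD115+Ly6C-, B cell genes (estimated correlation -0.04) went from a camera adjusted p of 1.62e-06 to 0.091. The lost calls thus do not by themselves show that correlation between genes made them. With the length trend removed, ribosomal protein genes turned up, at an adjusted p of 0.0069 for CD115-Ly6C- against CD115+Ly6C- and 0.174 for CD115-Ly6C- against CD115+Ly6C+. The log2 fold change of Rps27l became -0.05 for CD115+Ly6C+ against CD115+Ly6C-. Of 84 lists over the 3 comparisons, 12 lost and 4 gained a call with fry, 6 lost and 3 gained with no filter, and 0 lost and 2 gained with the replicate block. Of 297 calls of named genes, 4 were lost with DESeq2, 10 with limma, 10 with the replicate block and 22 with the length trend removed (besides the call of Rps27l that turned), and 68, 40, 41, 48, 28 and 18 without 1 library in the order of CD115+Ly6C-, CD115+Ly6C+ and CD115-Ly6C-.

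Genes setting CD115+Ly6C- apart at 2-fold were 0 higher and 24 lower. The first was 1 with the length trend removed, 1 with no filter, 1 with DESeq2 and 6 with no minimum fold, and 0 to 1 leaving out 1 library. The 24 became 12 with the length trend removed, 45 with no filter and 4 to 37 leaving out 1 library. For CD115+Ly6C+, 223 higher and 203 lower became 566 and 485 with no minimum fold, and 75 to 253 and 90 to 192 leaving out 1 library. For CD115-Ly6C-, 521 higher and 143 lower became 909 and 739 with no minimum fold, and 235 to 475 and 64 to 192 leaving out 1 library. With the shared libraries split, 1 for each comparison, CD115+Ly6C- had 0 higher and 8 or 5 lower, CD115+Ly6C+ 90 or 114 higher and 109 or 137 lower, and CD115-Ly6C- 347 or 239 higher and 151 or 63 lower. Fewer samples enter these fits. Depth limited the folds of genes with 1 to 3 counts in a subset, such as Pf4 and Tcf7, to wide intervals.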

Other observations

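Tests of the whole granule programme, of CD115+Ly6C+ cells among the sorted cells, of a mixture and of the split CD115+Ly6C- libraries were chosen only after the result was seen. All tests on the granule genes followed from the replicate gap, which was noticed first.

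The 14 late granule genes were higher in CD115+Ly6C- replicate 2 than in replicate 1 in 14 of 14 cases, by a median log2 ratio of 2.01 (SD 0.78), where the median of all genes was 0.0. A higher output of the whole granule programme was argued against by Elane, Mpo, Prtn3 and Ctsg, whose median was 0.14 (SD 0.42). Neutrophil-lineage cells or their RNA are a candidate source, since 14 neutrophil genes outside the fixed list rose by a median of 1.63 (SD 0.89; 14 of 14), though 9 of the 14 reached 1 CPM in CD115+Ly6C-, 14 in CD115+Ly6C+ and 6 in CD115-Ly6C-, and whether the sorted cells themselves express them was not tested. S100a8 stood at 62.1 and 245.9 CPM and Ngp at 61.7 and 215.1 CPM in the CD115+Ly6C- libraries, against 4646 and 3682 for Mpo; a lineage gate would remove mature neutrophils, but the labels used here name none. Cells of CD115+Ly6C+ in that library could not be told apart from this. Monocyte, macrophage and Fc receptor genes gained 0.39 times what the late granule genes gained (95% bootstrap interval over genes 0.15 to 0.74). Genes are not independent, and that interval leaves out the spread between libraries. A biological difference between the samples was not tested.

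CD115+Ly6C- libraries lay between those of CD115+Ly6C+ and CD115-Ly6C-, with Dntt, Flt3 and Ly6c2 at middle levels. A plain mixture of cells of the other subsets was argued against. The share of CD115-Ly6C- was 0.13 by 371 genes high there, and that of CD115+Ly6C+ was 0.13 by 163 genes high there. Their sum was 0.26 (95% bootstrap interval over genes 0.23 to 0.28). Genes are not independent, and this interval leaves out the spread between libraries. Noise of the shared CD115+Ly6C- libraries was argued against too, since such noise pushes both comparisons the same way. Of the 441 genes called in both comparisons, 90.9% went in opposite directions. With those libraries split between the comparisons, 93.8% or 94% of the genes called in both did. Opposite directions are the middle position seen gene by gene, so these shares are no separate support for it. A middle state of CD115+Ly6C- cells, as between lymphoid and myeloid progenitors, may underlie the order, but this hypothesis was itself not tested. Cells of the other subsets as a smaller part of the CD115+Ly6C- samples stay open too.

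Long and short transcripts moved apart between the subsets, with a Spearman's rho between length and log2 fold change of -0.33, 0.18 and 0.33 for CD115+Ly6C+ against CD115+Ly6C-, CD115-Ly6C- against CD115+Ly6C- and CD115-Ly6C- against CD115+Ly6C+. For CD115-Ly6C- against CD115+Ly6C+, ribosomal protein and other abundant genes alone were argued against as the cause, since rho was 0.31 without them over 10895 genes. The other comparisons were not tested in this way. Library preparation or RNA integrity varying between libraries could not be told apart from biology, as rho between the replicates was -0.07 in CD115+Ly6C-, -0.19 in CD115+Ly6C+ and -0.05 in CD115-Ly6C-, and the value in CD115+Ly6C+ was as large in size as the smallest between subsets. Ribosomal protein genes had medians of 0.37, 0.02 and -0.35 where genes of like length had 0.33, -0.21 and -0.54. A difference in transcript length use between the sorted subsets stays open as untested.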
